A study of Macaca fascicularis with 25 samples.

How the data were processed

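The data are read counts from 25 bulk RNA-seq libraries of Macaca fascicularis embryos. Per the labels' protocols, embryos with decidua were frozen in embedding medium and cryosectioned, populations of about 20 cells from putative regions were taken by laser microdissection, and libraries were made by Smart-seq2. Regions were chosen by their putative identity in the sections, per the labels' protocols, and no marker gene is named for that choice. The authors deposited 1 table of whole-number read counts per Ensembl gene identifier, with a column for each library. The submitters' processing notes name STAR 2.3.4 and RSEM without saying what each did. The genome build and the annotation are not given in the sources used here, and neither is whether the counts are RSEM estimates that were rounded, or whether counting used strand. Genes that share reads with close copies could therefore be over- or undercounted, and the counts carry no molecular identifiers.

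Columns were matched to samples by their titles, and 0 columns were without a sample. Groups were taken from the labels: hypoblast, epiblast, exmc and others at Day 18, sets E20_1 and E20_2 at Day 20, and the Day 16 library. Nothing in the labels says whether libraries of a group came from separate embryos. P-values therefore measure only the spread between captured regions, which may be technical, and are too small where regions of one group share an embryo and too large where regions of both groups compared do. In 39 pairs of libraries of one group, a chi-square statistic per gene of 37.6 to 264 lay above counting error. No library was therefore counted as a second deposit of another in its group, and pairs across groups were not checked in this way. This covers counting error only and does not show that libraries came from separate captures.

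Of the 28592 identifiers, 24618 had a count in at least 1 library. The gene table at hand, for the assembly T2T-MFA8v1.1, held no Ensembl identifiers, and 0 identifiers matched. The 27 gene lists with 492 symbols that had been fixed could not be read, so the list tests, the list levels in the Day 16 and Day 20 libraries and the fixed rule for named genes were not run. That rule had asked, per comparison, for the 8 genes with the largest change in each direction past the threshold, examples from each list and a set of lineage markers. In its place, after 0 calls had been seen, a new rule took identifiers with a mean of at least 20 CPM and no overlap of library ranges, and of these the 2 with the smallest unadjusted p in each direction over all 5 comparisons. These examples were picked from the data, so their p-values are not independent evidence.

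Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr within the groups, libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest, two-sided) was fitted to all 16 Day 18 libraries for the 4 Day 18 comparisons and to the 8 Day 20 libraries for the last. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 1.03 at Day 18 and 0.713 at Day 20. These designs and the alternatives were chosen before the data were examined, apart from those named as chosen later. Levels are TMM-scaled CPM, with SDs over libraries, and log2 CPM used a prior count of 2. Correlations between libraries were Spearman's, and those of deviations from group means were Pearson's. Their permutation tests used 100000 resamples, or all splits for the similarity of the Day 20 sets. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 served for these.

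Alternatives were DESeq2 1.42.0 (Wald test with its own filtering), limma 3.58.1 (voom with sample quality weights), DESeq2's size factors in edgeR, no filter on low counts, a filter of 10 CPM, only the compared groups in the fit, the replicate number as a block, detected genes as a covariate, a minimum fold of 2, and leaving out each library in turn. Up to 100 splits of the libraries, the one by label included, were refitted for each comparison. Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. Hypoblast and epiblast numbers were taken as paired, as these correlations were 0.254, 0.463 and 0.283 for numbers 1, 2 and 3. This pairing comes from the data, as the labels do not say what a number marks. It was not tested for these groups, where 3 numbers allow too few matchings.

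The test was tested on simulated data with 200 changed genes, drawn from the means, dispersions and totals of the real libraries. Each comparison was simulated once, with 15830 genes or, at Day 20, 13461. Recovery was read first for changed genes with a mean of at least 20 CPM. At 4-fold it was 3.70% of 27 such genes between epiblast and hypoblast and 8.11% of 37 between epiblast and exmc. It was 22.6% of 31 between hypoblast and exmc, 27.6% of 29 for others and 18.2% of 33 between the Day 20 sets. At 16-fold the test recovered 75.0%, 66.7%, 86.2%, 75.6% and 97.5% in the same order. Over changed genes of any mean CPM, recovery at 16-fold was lower, at 44.8%, 35.8%, 46.3%, 53.7% and 77.6% in that order. At 64-fold it was 54.5% to 68.2% over such genes in the Day 18 comparisons. Most of the simulated 4-fold changes were thus not called, and many larger ones were missed at low counts.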

Results

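RNA was measured in 25 libraries from embryos of the cynomolgus monkey, Macaca fascicularis. Each library came from a population of about 20 cells, collected by laser microdissection from cryosections of embryos with decidua and amplified by Smart-seq2, a full-length cDNA method for very small inputs. At Day 18 the labels gave 4 groups, with 3 libraries of hypoblast, 3 of epiblast, 6 labelled exmc and 4 labelled others. The epiblast is the layer that forms the embryo proper, and the hypoblast lies beneath it and contributes to the yolk sac. At Day 20 there were 8 libraries in 2 title sets of 4, E20_1 and E20_2, with no lineage in their labels. Day 16 had 1 library, so it has no replicate check and entered no comparison between groups.

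Total read counts per library ran from 2909114 to 10462278, with a median of 6757471. Hypoblast libraries were the deepest at Day 18, with a mean of 9211631 counts ± 1616669 (SD, n = 3), and exmc libraries the shallowest, with 4701988 counts ± 1682744 (SD, n = 6). The depth ranges of these groups did not overlap. Epiblast libraries held 5940326 counts ± 434736 (SD, n = 3) and the libraries labelled others 7048748 counts ± 1610481 (SD, n = 4). The Day 20 sets held 8402933 counts ± 574378 (SD, n = 4) in E20_1 and 7383094 counts ± 1485619 (SD, n = 4) in E20_2, and the Day 16 library held 4348127. Between 11777 genes, in exmc library 1, and 18034 genes, in exmc library 6, had a count above 0.

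**Figure D1:**
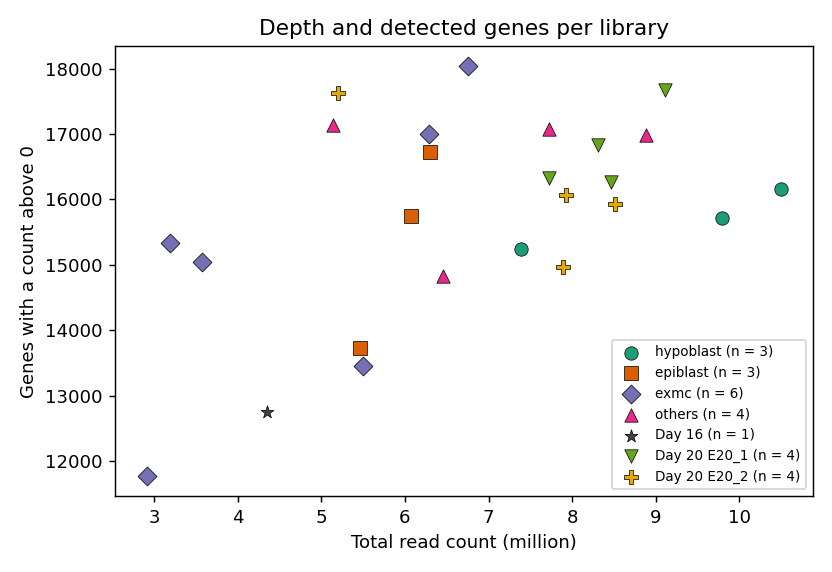
Each point is 1 of the 25 libraries, placed by its total read count on the x axis and its number of genes with a count above 0 on the y axis, with colour and shape for the group. The hypoblast libraries lie at 7386086 counts or more and the exmc libraries at 6757471 or fewer, and the exmc libraries span the whole range of detected genes.

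The counts are given by Ensembl gene identifier. The files do not pair these identifiers with gene names, and 0 of the 28592 identifiers matched the reference gene table, so genes appear below by identifier and no gene list or marker could be read.

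The first question was whether captured regions of the same Day 18 label resembled each other more than regions of different labels. No such likeness was found. The mean Spearman correlation of log2 CPM was 0.759 between libraries of one label and 0.791 between libraries of different labels, a difference of -0.0324 (one-sided permutation test over 16 libraries, p = 0.962). The size of this difference rests in part on single libraries, as it was -0.0141 without exmc library 4 and -0.00678 without exmc libraries 4 and 1. Exmc libraries had a mean correlation of 0.704 among themselves, with a range of 0.497 to 0.863, and of 0.818 without libraries 4 and 1. Libraries labelled others averaged 0.835 among themselves, hypoblast libraries 0.822 and epiblast libraries 0.817. Hypoblast and epiblast libraries correlated with each other at a mean of 0.839. The 3 pairs that share a replicate number averaged 0.886, with a range of 0.790 to 0.938. The 6 that do not averaged 0.815, with a range of 0.758 to 0.869. Leaving out the 3 same-numbered pairs gave a difference of -0.0292 between the means within and between labels (permutation p = 0.935). The most similar library carried the same label for 4 of the 16 libraries, against a mean of 3.60 by chance (permutation p = 0.492). Labels accounted for 17.0% of the variance of log2 CPM, where permuted labels accounted for a mean of 20.0% (permutation p = 0.884).

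**Figure D2:**
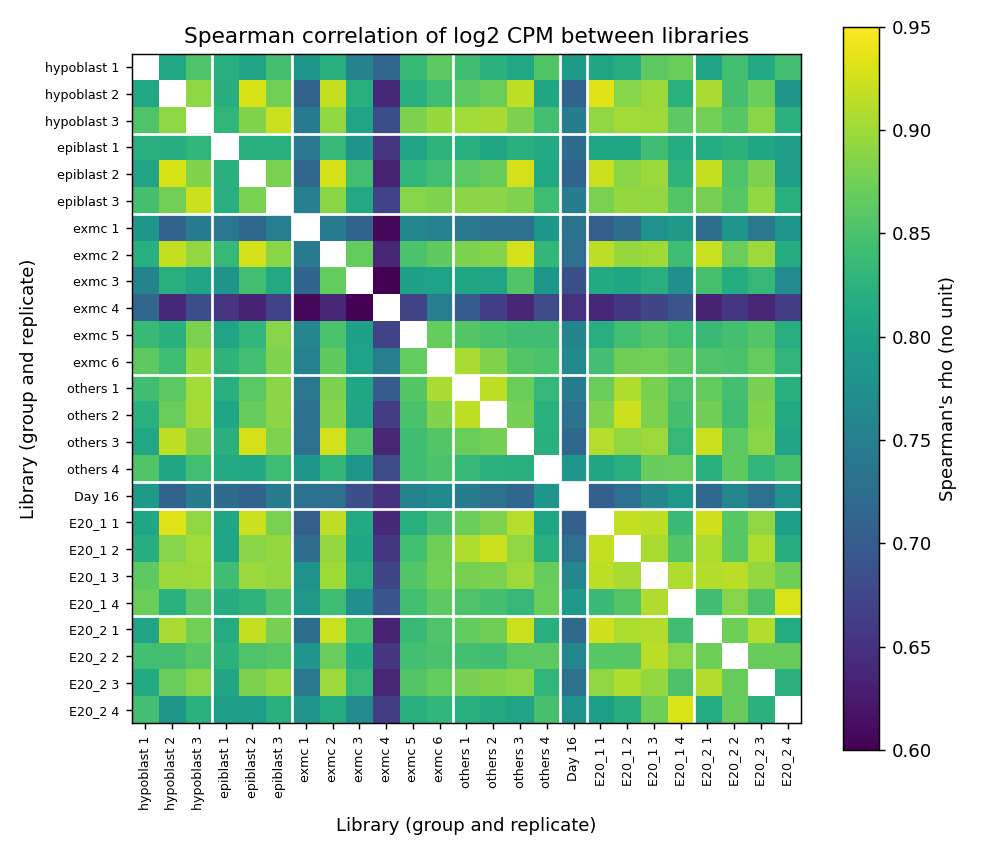
Each cell is the Spearman correlation of log2 CPM between a pair of the 25 libraries, over genes filtered on all 25, with white lines between the groups and the diagonal left blank. Values run from 0.600 to 0.933, the dark band is exmc library 4, and the Day 18 blocks along the diagonal average 0.759 against 0.791 off it when computed over the Day 18 libraries alone.

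Epiblast and hypoblast, the layers of the embryonic disc, were not separated at Day 18 by any gene in edgeR. None of the 15830 genes tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where 338 genes had an unadjusted p under 0.05 and chance gives 791.5 if libraries are independent. A pairing of hypoblast and epiblast libraries by number was assumed from their deviations and not tested. Over genes filtered on all 25 libraries, hypoblast libraries 2 and 3 correlated most with the epiblast library of their number. Hypoblast library 1 did not, with 0.820 for epiblast library 1 and 0.847 for epiblast library 3. The 3 other splits of these 6 libraries that part the numbers gave 270 to 357 genes. The smallest adjusted p in this edgeR fit, which had no pairing, was 1. With the replicate number as a block, edgeR still called 0 genes, and 220 had an unadjusted p under 0.05. In a fit of these 6 libraries alone, chosen after seeing the data, the block gave 580 such genes and a smallest adjusted p of 0.332. Without the block that fit gave 280 such genes. Among 7145 genes with a mean of at least 20 CPM, 680 had library ranges that did not overlap between the layers (9.52%, where chance gives 10% without pairing). DESeq2 called 32 genes, 8 higher and 24 lower in epiblast, and limma voom called 0. In all 32 of the DESeq2 genes every library of one layer had a count of 0, and in 31 a single library held more CPM than the other libraries of the higher layer together. The labels do not tie regions to embryos, so these p-values measure only the spread between captured regions, and are too small where regions of one group share an embryo and too large where regions of both groups do.

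Epiblast and exmc regions showed no gene past the threshold in edgeR either. Of 15830 genes tested, edgeR called 0, with 905 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.849. Library ranges did not overlap for 241 of 7565 genes with a mean of at least 20 CPM (3.19%, where chance gives 2.38%). The identifier ENSMFAG00000032531 stood at 6.71 CPM ± 2.14 (SD, n = 3) in epiblast and 48.7 CPM ± 40.9 (SD, n = 6) in exmc, with no overlap between their libraries. Its log2 fold change of -2.86 (SE 0.733) had an adjusted p of 0.849 in edgeR, an adjusted p of 0.786 in limma voom and an adjusted p of 0.00298 in DESeq2. DESeq2 called 76 genes, 1 higher and 75 lower in epiblast, of which 61 had more CPM in a single library than in the other libraries of the higher group together, and limma voom called 0. These p-values carry the same limit on regions that share an embryo.

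In the main fit, hypoblast against exmc gave the most genes at an unadjusted p under 0.05 of the 4 Day 18 comparisons. Again none passed the threshold in edgeR. That rank depended on the settings, as with no filter on low counts it had 1669 such genes and others against the named lineages 1856. Of 15830 genes, 1140 had an unadjusted p under 0.05 and the smallest adjusted p was 0.614. Library ranges did not overlap for 371 of 7643 genes with a mean of at least 20 CPM (4.85%, where chance gives 2.38%). ENSMFAG00000038514 had 459 CPM ± 161 (SD, n = 3) in hypoblast and 138 CPM ± 39.3 (SD, n = 6) in exmc, a log2 fold change of 1.74 (SE 0.366, edgeR adjusted p = 0.614). Epiblast libraries had 242 CPM ± 116 (SD, n = 3) of it and libraries labelled others 244 CPM ± 38.2 (SD, n = 4). ENSMFAG00000032376 had 481 CPM ± 176 (SD, n = 3) in hypoblast and 172 CPM ± 48.5 (SD, n = 6) in exmc, a log2 fold change of 1.49 (SE 0.315, edgeR adjusted p = 0.614). The adjusted p of both was 0.0308 in limma voom, and in DESeq2 it was 0.0298 for the former and 0.0201 for the latter. In this comparison limma voom called 61 genes, 57 of them higher in hypoblast, while DESeq2 called 74, of which 61 were lower in hypoblast, and 11 genes were called by both. Of the DESeq2 calls, 44 had more CPM in a single library than in the other libraries of the higher group together and 28 had no overlap of library ranges, against 2 and 46 of the limma voom calls. Without hypoblast library 2, 645 of the 16978 genes then tested had an unadjusted p under 0.05. Hypoblast libraries were also deeper than every exmc library, and the same limit on shared embryos applies.

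The libraries labelled others were set against the mean of the named lineages, epiblast, hypoblast and exmc. In edgeR 0 of 15830 genes passed, 462 had an unadjusted p under 0.05, and the smallest adjusted p was 0.369. The 462 depended on the filter, with 1856 of 23646 genes without it and 144 of 11205 with the filter of 10 CPM, and 0 called in both. DESeq2 called 19 genes, 14 higher and 5 lower in others, of which 16 had more CPM in a single library than in the other libraries of the higher side together, and limma voom called 1. That gene, ENSMFAG00000044728, named because it was the only one called by both and so chosen after its values were seen, had counts of 329, 67, 38 and 6 in the libraries labelled others. Of the 12 libraries of the named lineages, 10 had a count of 0, epiblast library 3 had 3 and exmc library 5 had 1. It ranged from 0.925 to 38.6 CPM in others and from 0 to 0.477 CPM in the named lineages. Its log2 fold change was 7.81 (SE 1.30, adjusted p = 0.369) in edgeR, with an adjusted p of 0.00645 in limma voom and of 0.00237 in DESeq2. Among 7515 genes with a mean of at least 20 CPM, 1 had library ranges that did not overlap (0.0133%, where chance gives 0.110%). Leaving out 1 library moved the 462 genes to 703 without hypoblast library 1, 713 without hypoblast library 3, 699 without epiblast library 2 and 296 without others library 2. The filter then kept 16896, 16983, 16929 and 15631 genes in the same order, so these counts are over different sets of genes. The limit on regions that share an embryo applies here as well.

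At Day 20 the sets E20_1 and E20_2 were compared, although the labels do not say what a set is. EdgeR called 0 of 13461 genes, with 838 at an unadjusted p under 0.05 against 673.1 by chance and a smallest adjusted p of 0.784. ENSMFAG00000001982 had 64.1 CPM ± 12.0 (SD, n = 4) in E20_1 and 149 CPM ± 32.1 (SD, n = 4) in E20_2, with a log2 fold change of -1.21 (SE 0.274). Its adjusted p was 0.784 in edgeR, 0.497 in limma voom and 0.0370 in DESeq2. DESeq2 called 18 genes, 15 higher and 3 lower in E20_1, and limma voom called 0. All 18 had library ranges without overlap, and in 0 of them did a single library outweigh the rest of its set. Library ranges did not overlap for 420 of 7126 genes with a mean of at least 20 CPM (5.89%, where chance gives 2.86%). Over the genes tested at Day 20, correlations within a set averaged 0.820 and those between the sets 0.829, and 20 of the 35 splits of the 8 libraries gave a difference as large (exact permutation test, one-sided, p = 0.571). The 838 genes became 502 without E20_1 library 1 and 1413 without E20_1 library 4, where the filter kept 14089 and 14084 genes. The limit on shared embryos applies to the Day 20 p-values too.

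**Figure D3:**
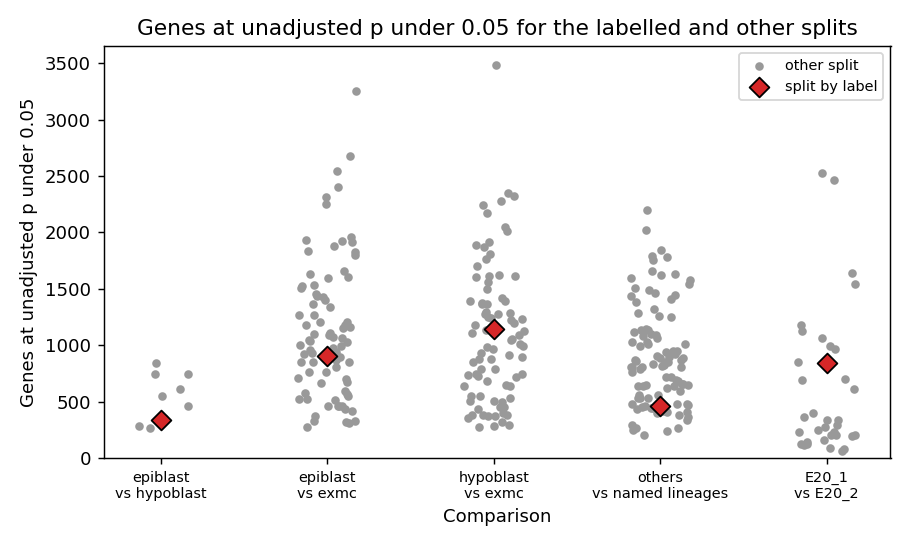
Each grey point is a split of the libraries of a comparison other than the one by label, the red diamond is the split by label, and the y axis counts genes at an unadjusted p under 0.05 in edgeR. The diamonds lie at 338, 905, 1140, 462 and 838 genes, and other splits reach 839, 3253, 3482, 2196 and 2529.

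**Figure D4:**
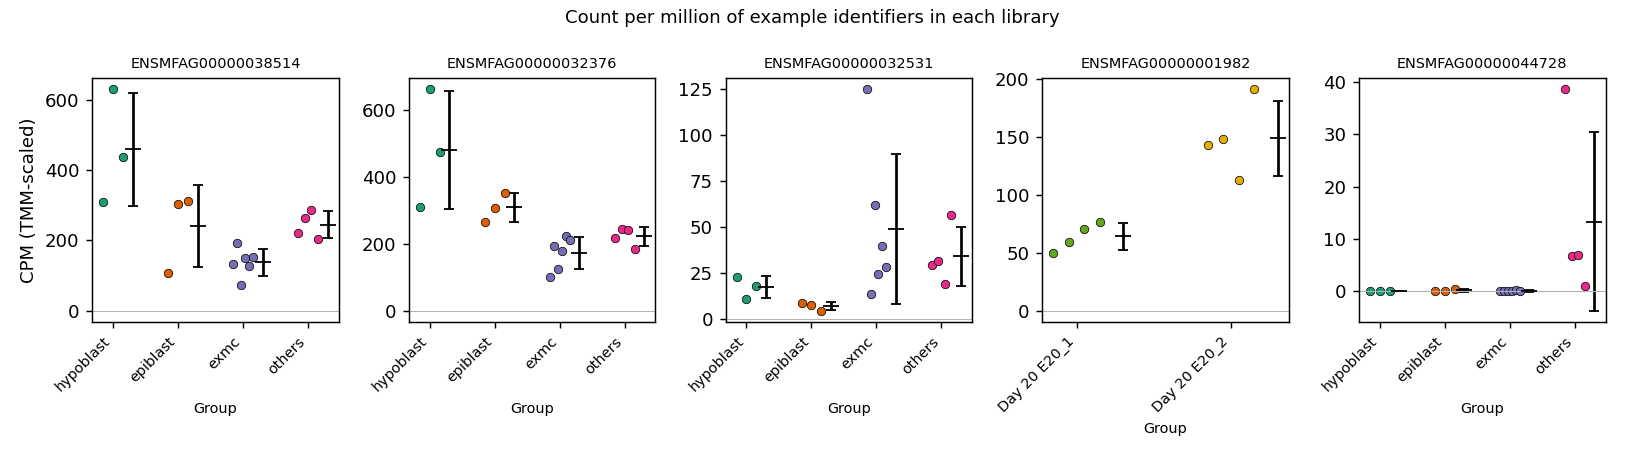
Each panel shows 1 identifier, with TMM-scaled CPM on the y axis, a point for each library of the group on the x axis, and the mean and SD beside the points. In the 2 left panels hypoblast lies above exmc, in the third exmc lies above epiblast, in the fourth E20_2 lies above E20_1, and in the last the libraries labelled others reach 38.6 CPM where the named lineages stay at or below 0.477.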

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

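Of the tests described here, those of other splits, of the group sizes, of the 2 least similar libraries, of replicate numbers, of nearest libraries and of regressing out detected genes were chosen only after the result was seen. Values far from the rest of their group were searched for in 32 sets of libraries, of which chance alone gives about 1.60, and 4 were found.

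In exmc library 3, the most abundant gene, ENSMFAG00000000004, took 32.2% of all counts (95% Wilson interval 32.2% to 32.3%, for counting error only), where the other exmc libraries gave it 10.7% to 13.9%. The 10 most abundant genes took 44.0% of its counts (95% Wilson interval 43.9% to 44%), against 15.9% to 22.7% in the others. Library 4 of the group labelled others had 14828 detected genes, where the rest of that group had 16978 to 17142. Library 4 of the Day 20 set E20_2 had a mean correlation of 0.836 with its own set over genes filtered on all 25 libraries, a gene set that gives higher values than the Day 20 genes alone, against 0.866 to 0.870 for the rest. The Day 16 library, which no comparison used, held 25 genes with more than 3 counts that had 0 counts in the 24 other libraries, and each of those had between 9 and 90 such genes of its own.

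The pattern most worth following up was that Day 18 libraries of one label were not closer to each other than to libraries of other labels. Sequencing depth was argued against, since the difference was -0.0322 after thinning every library to one total (permutation p = 0.961). A linear effect of the number of detected genes was argued against as well, with a difference of -0.0293 after regressing that number out of each gene (permutation p = 0.945). Such a regression does not remove the noise from genes missed in a library, so other effects of detected genes stayed open. A step shared by replicate number stayed open: same-numbered libraries of different labels deviated together at Day 18 (permutation p = 0.0437) while the same test at Day 20 did not pass (permutation p = 0.208). Labels that do not describe the captured cells stayed open too, since 4 of 16 libraries had a nearest library of their own label, and a biological likeness of these regions was not tested because no marker gene could be read.

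That edgeR called no gene between the Day 18 groups was set against 2 technical explanations. Hiding of differences by the least similar libraries stayed open: without exmc libraries 4 and 1 edgeR still called 0 genes in each of the 4 comparisons, but in 3 of them more genes had an unadjusted p under 0.05 (622, 1623 and 667, against 338, 1140 and 462) and the fit had fewer libraries. Groups too small for any call at all were argued against for hypoblast and exmc, where another split of the same 9 libraries called 143 genes. That split set hypoblast library 1 and exmc libraries 4 and 6 against the rest. It does not show that changes between lineages would be called. In this comparison the test called 25 of 29 simulated 16-fold changes but 7 of 31 simulated 4-fold changes at 20 CPM or more. Over changed genes of any mean CPM it called 31 of 67 at 16-fold. Group size thus stays open for small changes and for genes below 20 CPM. The simulation drew each gene independently, without libraries that deviate as a whole, so it does not settle large changes in the real libraries either. For epiblast and hypoblast another split of those 6 libraries called at most 0 genes, which decides nothing, and group size stays open. At this size the test called 24 of 32 simulated 16-fold changes but 1 of 27 simulated 4-fold changes at 20 CPM or more. Over changed genes of any mean CPM it called 30 of 67 at 16-fold. Regions that hold a mixture of cells remain untested.

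Other splits of the same libraries measured whether the counts of genes at an unadjusted p under 0.05 exceeded chance. Chance could not be excluded for epiblast against exmc (905 genes, 51 of 84 splits as large, highest other 3253), hypoblast against exmc (1140 genes, 37 of 84 splits, highest other 3482), others against the named lineages (462 genes, 82 of 100 splits drawn, highest other 2196) or the Day 20 sets (838 genes, 11 of 35 splits, highest other 2529). For epiblast against hypoblast the 10 splits are too few for a share under 0.05, with 8 splits as large, a real value of 338 and a highest other of 839. The 3 other splits that part all 3 replicate numbers as the real one does gave 270 to 357 genes and the 6 that do not gave 464 to 839. At Day 20 the other splits had a median of 312 genes. Those that part all replicate numbers gave 91 to 333, below the 838 by label. Numbers were not taken as paired at Day 20, and such splits are too few for a share under 0.05, so chance stays unexcluded there. Some splits called genes in edgeR where the labels called none in edgeR. These were 6 of 84 for epiblast and exmc, 8 of 84 for hypoblast and exmc, 8 of 100 for others and 1 of 35 at Day 20. Whether such shares exceed chance was not tested, so no structure other than the labels is inferred. The 22 Day 18 splits called 1 to 196 genes, 16 of them with exmc libraries 4 and 6 both in the smaller group. The Day 20 split, libraries 1 and 2 of E20_1 with libraries 1 and 3 of E20_2 against the rest, called 568.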

How the results depend on the processing

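Leaving out the 2 least similar libraries, the block within 6 libraries, the tests of others against each lineage, leaving out same-numbered pairs, regressing out detected genes in the similarity test and the 20 CPM restriction were chosen after seeing the data. In edgeR every alternative run kept 0 called genes in the 5 comparisons. The DESeq2 Wald test called 32 genes (epiblast against hypoblast), 76 (epiblast against exmc), 74 (hypoblast against exmc), 19 (others) and 18 (Day 20 sets), and limma voom called 61 between hypoblast and exmc and 1 for others, with 0 elsewhere. The cause was not tested. Leaving out 1 library at a time kept 0 calls, with 265 to 462, 608 to 1070, 645 to 1452, 296 to 713 and 502 to 1413 genes at an unadjusted p under 0.05 in the same order. The filter on low counts was applied anew in each of these fits, so the genes tested differed from the main fit. The replicate block called 0 genes in each comparison, with 220, 557, 1010, 589 and 1465 genes at an unadjusted p under 0.05, so it changed no call. Within the 6 epiblast and hypoblast libraries alone it also called 0 (580 genes at an unadjusted p under 0.05, against 280 in that fit without it). Numbers were not taken as paired elsewhere. Deviations correlated at -0.155 to 0.384 for epiblast and exmc, -0.0383 to 0.486 for hypoblast and exmc, and -0.146 to 0.0177 for hypoblast and others. They gave -0.201 to 0.0137 for epiblast and others, -0.133 to 0.310 for exmc and others, and -0.249 to 0.705 for the Day 20 sets. Others called 0 genes by edgeR against epiblast (393 at an unadjusted p under 0.05), hypoblast (447) and exmc (609), and any difference among the 4 groups called 0 (720). The similarity difference stayed negative throughout, from -0.0425 to -0.0141 with 1 library left out, and -0.00678 (permutation p = 0.729) without the 2 least similar. The log2 fold changes of the 4 example identifiers, whose direction the choice of non-overlapping libraries largely fixed, ranged over the alternatives as follows: ENSMFAG00000038514 at 1.42 to 1.96, ENSMFAG00000032376 at 1.16 to 1.73, ENSMFAG00000032531 at -3.05 to -2.13 and ENSMFAG00000001982 at -1.38 to -1.09. Not run were the list tests, list levels and the fixed named genes, for lack of gene names, and a fit with only the compared groups for others, which is the same fit.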

Other observations

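All tests in this part were chosen only after the result was seen. The most similar pairs of libraries shared no label, though several of these pairs hold a Day 20 library, whose label names no lineage. Among the 300 pairs of the 25 libraries, over genes filtered on all 25, 39 pairs (13%) shared a label, and of the 10 pairs with the highest correlation 0 did. The highest, 0.933, was between hypoblast library 2 at Day 18 and library 1 of E20_1 at Day 20. Libraries numbered 4 of both Day 20 sets correlated at 0.931, hypoblast library 2 with epiblast library 2 at 0.929, epiblast library 2 with others library 3 at 0.928 and epiblast library 2 with exmc library 2 at 0.927. No test of these pairs was made, since they were picked as the highest.

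A library's mean similarity to the other Day 18 libraries rose with its number of detected genes. The labels give no batch within which to repeat this. Fewer detected genes mean more tied zeros, which alone can lower a rank correlation, so the relation may come in part from the measure. Over 16 libraries, Pearson's r with detected genes was 0.779 (permutation p = 0.000870, adjusted p = 0.00261 by Benjamini-Hochberg over 3 relations) and Spearman's rho 0.788 (permutation p = 0.000540, adjusted p = 0.00162). Without the 2 libraries farthest from the median, r was 0.749. For total counts, r was 0.469 (permutation p = 0.0629, adjusted p = 0.0944) and rho 0.503 (permutation p = 0.050, adjusted p = 0.050), and r fell to 0.258 without the 2 farthest, so that relation rests on them. For the share of the most abundant gene, r was -0.325 (permutation p = 0.144, adjusted p = 0.144) and rho -0.550 (permutation p = 0.0301, adjusted p = 0.0451), with r at -0.437 without the 2 farthest. Exmc libraries 4 and 1 had the lowest mean similarity, 0.592 and 0.679.

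The Day 16 library correlated with the 24 others at 0.650 to 0.791, with a mean of 0.738. ENSMFAG00000044728, seen in the libraries labelled others, had a count of 0 in the Day 16 library, and 1 of the 8 Day 20 libraries had counts of it, with 11 in library 1 of E20_1. Genes above 20 CPM in both libraries of a pair and below 1 CPM in every other Day 18 library were searched for in 120 pairs and no pair had more than 2, too few to test.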
